A study of Rattus norvegicus with 36 samples.

How the data were processed

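RNA sequencing libraries of 4 rat brain regions were compared between blast and sham exposure, 6 weeks after exposure: hippocampus (5 blast, 5 sham), amygdala (5 blast, 4 sham), anterior cortex (3 blast, 5 sham) and cerebellum (5 blast, 4 sham), 36 libraries in 8 groups. Per the labels the material was total RNA extracted with Qiazol and RNeasy columns, and libraries were made with a NEBNext Ultra kit; whether poly-A RNA was selected is not given in the sources used here. CASAVA is named in the submitters' processing notes, without a version. The aligner, the read counter, the genome build, the annotation release and the authors' test are not given in the sources used here, so coordinates are printed as deposited and hold for an unnamed build.

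The authors deposited 1 table per region. Its count columns hold whole read counts per gene and library, per the file headers. A further column per library holds a signal that the authors normalized: in each library it is the count divided by 1 factor, and size factors recomputed here by DESeq2's method were 1 times the deposited ones in hippocampus and cerebellum, 0.9961 to 0.9972 times in amygdala and 1.0209 to 1.0228 times in anterior cortex. The deposited log2 fold changes are those of blast over sham, and are smaller than the ratios of the group means, as shrunken estimates are. The deposited p-value columns hold the authors' p-values and adjusted p-values. The counts alone entered the tests described here, the authors' adjusted p-values are quoted where named, and 36 columns of FPKM values were not used here. The tables hold 23535 genes in hippocampus, 24044 in amygdala, 23472 in anterior cortex and 23147 in cerebellum, 26142 genes in any table and 21121 in all; 25 gene names had been turned into dates by a spreadsheet, so genes were joined by Ensembl ID.

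Libraries held 15426786 to 23460322 counts on genes. Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. In each region genes were filtered with filterByExpr, scaled by TMM and tested by edgeR's quasi-likelihood F test (glmQLFit, glmQLFTest) of blast against sham, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 values for lists used a prior count of 2. Standard errors belong to the log2 fold changes of these fits, and SDs to CPM (counts scaled by library size) between libraries.

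Before the data were examined, 40 gene lists with 637 distinct genes were fixed, of which 22 genes were in no table, together with 8 genes by name (Gfap, Aif1, Vwf, Grm2, Grm3, Mapt, Fkbp5 and Fos). The lists named most often are microglia, immediate early genes, choroid plexus, nuclear oxidative phosphorylation and cytosolic ribosomal proteins. Lists can share genes, such as C1qa, C1qb and C1qc in microglia and complement, or Tac1 and Penk in striatal neurons and stress and fear peptides. Lists with at least 5 measured genes were tested by limma's camera at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a region, and again with the correlation estimated from the data and by limma's fry. Lists of markers of unipolar brush cells and Golgi cells were added after the results for Grm2 were seen. Members of a list were also adjusted over the list alone.

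The naming rule took, in each region, called genes with a symbol, at most 12 in each direction, whose groups did not overlap, or all called genes with a symbol if fewer than 24 qualified; called members of the lists, at most 4 per list; and, where fewer than 6 genes were called, the 6 genes with a symbol of smallest p in each direction, given as not past the threshold, besides the 8 fixed genes. Other members of lists quoted as examples have small p in their list and region and were chosen after their values were seen, as were AABR07066510.1 and LOC108348106.

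Differences between regions were tested over all 36 libraries by edgeR's quasi-likelihood F test of the 3 region by treatment terms, and for lists, after the results by region were seen, by camera on the difference of 2 regions. Fold changes of 2 regions were compared by Pearson's r, with 100 relabellings of the numbers in the titles as blast or sham, the same in every region. The numbers recur between regions, so they were also used as a block. Values averaged over regions by number were tested with limma (limma-trend), and a fit of all libraries used limma-voom with a correlation within numbers.

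The pipeline was tested on simulated counts, drawn at the spread of these libraries with 67, 67 and 66 genes changed 1.5, 2 and 4-fold. It recovered 38.8%, 71.6% and 90.9% of them in hippocampus, 55.2%, 85.1% and 92.4% in amygdala, 40.3%, 67.2% and 89.4% in anterior cortex, 50.7%, 77.6% and 93.9% in cerebellum, 29.9%, 65.7% and 75.8% for differences between regions and 61.2%, 89.6% and 98.5% by number, with 9, 10, 15, 7, 2 and 12 false calls. A list shifted by 0.3 on the log2 scale was recovered in every region, with an adjusted p of at most 0.00172 with an estimated correlation. The simulated genes were drawn independently, while members of real lists move together (estimated correlation 0.376 for the shifted list, synaptic proteins, over all 36 libraries). This recovery therefore does not show what the test with an estimated correlation can detect in these data. For genes, all changes were simulated in the same run, which eases the adjusted threshold. Where few genes change, the recovery would be lower. In cerebellum Grm2, at a log2 fold change of -0.97 and an unadjusted p of 1.853e-05, had an adjusted p of 0.141 by edgeR. Libraries of a number were also drawn independently of each other.

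The alternatives tried were RLE size factors, DESeq2's Wald test, limma-voom with sample quality weights, no filter, a mean of at least 50 counts, 1 surrogate variable, leaving out each library in turn, the estimated correlation and fry for lists, the number as a block, and genes above the median of expression in both regions or numbers shared by both regions for the correlations. A robust spread estimate and the choroid plexus score as a covariate were chosen after seeing the data.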

Results

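Gene expression was measured by RNA sequencing in 4 brain regions of rats, 6 weeks after the animals were exposed to a blast or to a sham procedure. A blast passes a pressure wave through the head and is used in animals to study the brain injury that explosions leave behind. The pressure and the number of exposures are not given in the sources used here. The 36 libraries came from hippocampus (5 blast, 5 sham), amygdala (5 blast, 4 sham), anterior cortex (3 blast, 5 sham) and cerebellum (5 blast, 4 sham). Reads counted on genes per library numbered 15426786 to 23460322 in hippocampus, 15667480 to 21643208 in amygdala, 15837696 to 21988689 in anterior cortex and 16535645 to 18881931 in cerebellum. Libraries are named here by their group and the number in their title, and the blast numbers 1, 2, 5, 6 and 9 and the sham numbers 10, 12, 13, 16 and 18 recur between regions. The labels do not say that each number is a separate animal, so the p-values measure only the spread between these libraries, part of which may be technical. Every pair of libraries of one group differed by at least 6.018 times the variance of sampling noise, so none repeats the counts of another. Whether 2 libraries of a group came from 1 animal cannot be told from this. The 40 gene lists, the tests of genes and lists in each region, the test of genes between regions, the correlations and the rule for naming genes were chosen before the data were examined. Other tests, among them those of lists between regions, of values averaged by number and of gene length, were chosen later. Members of a list that are quoted as examples outside that rule were picked after their values were seen, for their small p in the list and region.

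In hippocampus, the region of memory formation, blast libraries carried more RNA of microglia, the resident immune cells of the brain, and less of the immediate early genes, which neurons switch on with activity. All 17 measured microglial markers were higher, by a median of 0.24 on the log2 scale. All 20 immediate early genes were lower, by a median of -0.27. Complement genes rose too, with 12 of 14 higher and a median of 0.21, though C1qa, C1qb and C1qc are in the microglial list as well. The ionotropic glutamate receptors, the channels of fast excitatory signalling, fell, with 15 of 15 lower and a median of -0.18. Ribosomal protein genes rose, with 42 of 43 higher and a median of 0.20. These 5 lists passed limma's camera test at its preset correlation, with Benjamini-Hochberg adjusted p of 2.66e-07, 1.63e-08, 0.00187, 0.000496 and 6.66e-19 in that order, and kept their calls whichever library was left out. With the choroid plexus score as a covariate, a check chosen after seeing the data, the calls of complement and ionotropic glutamate receptors ended (camera adjusted p = 0.391 and 0.614). None of the 5 passed when the correlation between genes was estimated from the data (adjusted p = 0.462 with an estimated correlation for each). The microglial rise was not alone among cell types. From sham to blast the mean log2 CPM went from 7.688 to 7.8 for astrocyte genes and from 4.498 to 4.642 for endothelial genes. It went from 2.784 to 3.248 for fibroblast and matrix genes (SD 0.15 in sham, 0.686 in blast). For blood cell genes it went from 4.114 to 4.712 (SD 0.769 and 0.538). Means of excitatory and inhibitory neurons were lower, but within the spread of libraries. They went from 6.937 (SD 0.055) to 6.897 (SD 0.136) and from 4.338 (SD 0.116) to 4.294 (SD 0.14).

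Single members showed what these medians are made of, although none passed the test over all genes (edgeR adjusted p of 0.816 for each gene named in this paragraph). P2ry12, the receptor by which resting microglia sense released nucleotides, had 18.5 CPM (counts scaled by library size) in sham and 25.1 CPM in blast libraries, a log2 fold change of 0.44 (SE 0.13, n = 5 and 5). Csf1r, which microglia need to survive, differed by 0.24 (SE 0.08), and C3, the central component of complement, by 0.73 (SE 0.26). Among the immediate early genes, Bdnf, a growth factor released by active neurons, went from 50.1 to 35.0 CPM (log2 fold change -0.52, SE 0.20). Arc, which remodels synapses, went from 89.45 to 63.0 CPM (-0.50, SE 0.22) and Egr1 from 94.98 to 71.5 CPM (-0.41, SE 0.18). No immediate early gene and no microglial marker passed when adjusted over its list alone.

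Choroid plexus RNA stood out in the same libraries. All 13 measured markers of this fluid-secreting tissue of the ventricles were higher in blast libraries, by a median log2 fold change of 4.07. All 13 passed when adjusted over the list alone (camera adjusted p = 8.73e-07; adjusted p = 0.462 with an estimated correlation). The rise was uneven: Ttr, one of them, reached 7146 CPM in blast 6 and 2274 CPM in blast 2, against 458.7 CPM in sham 12 and at most 211.1 CPM in the other 7 libraries. The library blast 6, whose title carries an added "re" that the labels do not explain, also had the highest score for myelin genes and the lowest for synaptic genes. Myelin genes were higher by a median of 0.38, with 17 of 17 up. Of the synaptic protein genes 20 of 24 were lower, by a median of -0.10 (camera adjusted p = 0.000281 and 0.00108; adjusted p = 0.462 with an estimated correlation for both). Both calls ended without blast 6 (adjusted p = 0.449 and 0.283). The 6 measured markers of dentate granule cells, the main neurons of the dentate gyrus, were all lower, by a median of -0.28 (camera adjusted p = 0.00191; adjusted p = 0.462 with an estimated correlation), with Dsp at -0.55 (SE 0.17; adjusted p = 0.0467 over the list alone). That call also ended without blast 6 (adjusted p = 0.101).

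**Figure D1:**
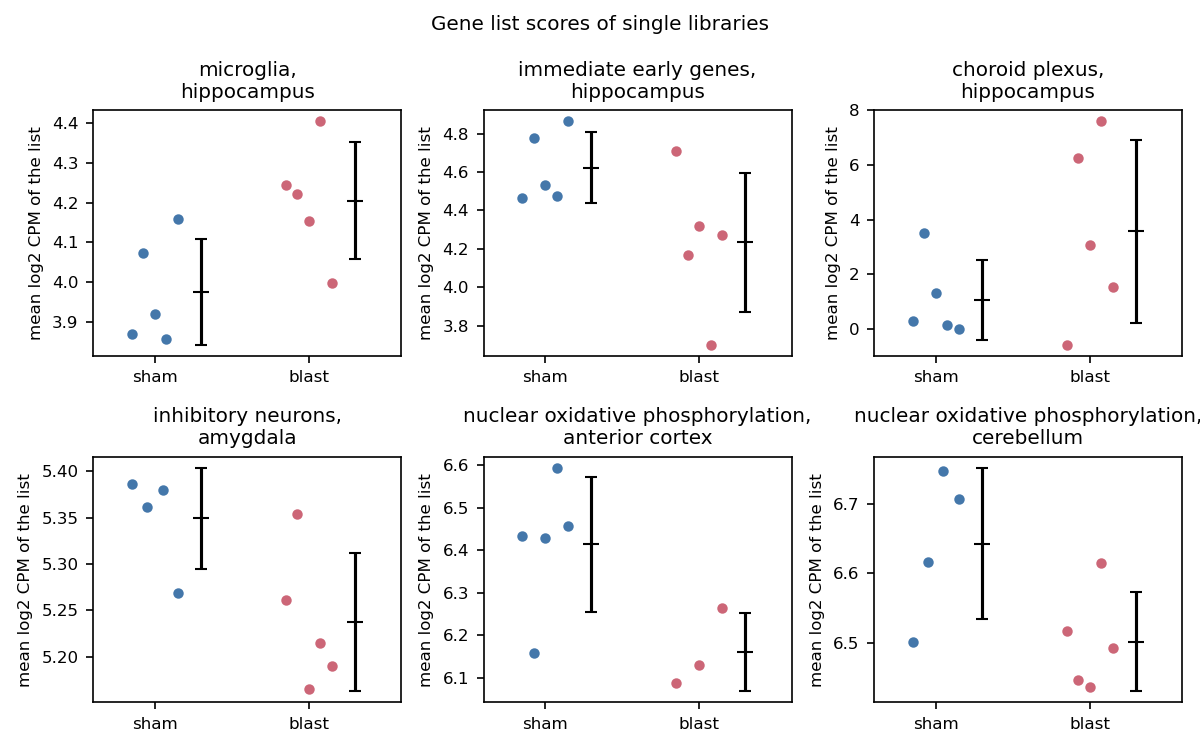
Each point is 1 library (blue sham, red blast), the vertical axis is the mean log2 CPM of the genes of 1 list in 1 region, and the bars give the group mean and SD. In hippocampus the microglial score averaged 3.98 in sham and 4.21 in blast libraries and the immediate early gene score 4.62 and 4.23, while the choroid plexus score spread widely in blast libraries (SD 3.36).

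In all, 19 of the 40 lists passed in hippocampus by camera, 13 up and 6 down, and 0 with an estimated correlation (smallest adjusted p = 0.462). When blast 6 was left out 11 passed, 9 of them among the 19. With the choroid plexus score of each library as a covariate, a check chosen after seeing the data, 7 lists passed. Microglia, astrocytes, endothelium, immediate early genes and ribosomal proteins were the 5 of these that were among the 19. In the list of monoamine receptors and transporters, 13 of 18 genes were lower (camera adjusted p = 0.0475; adjusted p = 0.462 with an estimated correlation). The mean of the list was 0.02 against a median of -0.08. The call ended without sham 13, sham 16, blast 1, blast 2, blast 6 or blast 9 (adjusted p up to 0.15). The limma fry test, which asks whether a list moves on balance one way without comparing it with other genes, called 0 lists here (smallest adjusted p = 0.473).

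No single gene passed in hippocampus by edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.816). Of the 15349 genes 805 had an unadjusted p below 0.05, where chance gives 767.5. DESeq2 called 1 gene and edgeR 1 gene without blast 9. In the authors' deposited values 0 genes pass. Blast and sham libraries did not overlap for 130 genes (0.85%, where chance gives 0.794%). The 6 genes of smallest p in each direction, which the naming rule takes, all had an adjusted p of 0.816. Higher in blast libraries was Ccdc152 (ENSRNOG00000039473; chromosome 2, 53116101 to 53140637), at 11.6 ± 1.29 CPM in sham and 16.2 ± 2.24 CPM in blast libraries (SD, n = 5 and 5; log2 fold change 0.47, SE 0.12). Also higher were Lsp1, a leukocyte protein, at 0.97 (SE 0.24), and Mtdh, Copz2, Rpl37a and Upk1a, at 0.44 to 1.40. Lower was Fundc2, a protein of the mitochondrial outer membrane (ENSRNOG00000024066; chromosome 18, 402295 to 407954), at 33.4 ± 2.71 and 23.9 ± 4.05 CPM (-0.48, SE 0.11). Pnpla1, a lipid-metabolising enzyme (ENSRNOG00000028622; chromosome 20, 6102277 to 6143707), was at 8.70 ± 6.50 and 1.76 ± 0.74 CPM (-2.29, SE 0.57). Also lower were Serinc2 at -0.72 (SE 0.18), and Rrn3, Ndst3 and Pla2g4f, at -0.37 to -1.12. Rpl37a belongs to a family with many near-identical copies in the genome, so its count is uncertain.

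In amygdala, the region of fear learning, genes of inhibitory neurons were lower and genes of blood vessels higher in blast libraries. The 14 measured markers of inhibitory neurons had a median log2 fold change of -0.18, with 10 lower. Of the measured subunits of the GABA-A receptor, through which inhibitory neurons act, 11 of 12 were lower, by a median of -0.15. Endothelial and blood-brain barrier genes rose by a median of 0.18, with 15 of 16 higher, and all 6 blood cell genes were higher, by a median of 0.43. By camera the adjusted p of these 4 lists were 0.00601, 0.00125, 4.04e-05 and 0.00125, and all 4 calls held whichever library was left out. None held with an estimated correlation (adjusted p = 0.286 for inhibitory neurons and 0.411 for the other lists).

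Gad2, one of the enzymes that make the inhibitory transmitter GABA (ENSRNOG00000018200; chromosome 17, 89171250 to 89238040), fell from 272.6 ± 21.9 CPM in 4 sham libraries to 210.3 ± 19.97 CPM in 5 blast libraries when adjusted over its list alone (edgeR adjusted p = 0.00782), a log2 fold change of -0.37 (SE 0.08). Every blast library lay below every sham library. Over all genes its adjusted p was 0.901 by edgeR and 0.0396 by DESeq2. The authors' deposited values are 0.0093 with a log2 fold change of -0.31. Over all settings tried the adjusted p ran from 0.0396 to 0.994. Gad1, the other such enzyme, differed by -0.21 (SE 0.07), and Slc32a1, which loads GABA into vesicles, by -0.22 (SE 0.09), both without passing. Markers of striatal neurons, which lie next to the amygdala and are themselves largely inhibitory, moved with this group. Of these 11 of 14 were lower, by a median of -0.19 (camera adjusted p = 0.006; adjusted p = 0.411 with an estimated correlation; 0.0693 by camera without sham 12). Among them were the dopamine receptor Drd2 at -0.72 (SE 0.27) and the adenosine receptor Adora2a at -0.99 (SE 0.38). Of the genes of stress and fear peptides, 14 of 19 were lower, by a median of -0.17 (camera adjusted p = 0.0124; adjusted p = 0.297 with an estimated correlation; 0.0644 by camera without sham 12). Tac1, the precursor of substance P, was the 1 member past the threshold over the list alone, at -0.60 (SE 0.16; adjusted p = 0.0492). It is in the list of striatal markers as well.

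Glutamate receptors were lower, and genes of microglia, complement and antigen presentation higher, in amygdala, in calls that each ended without some library. Metabotropic glutamate receptors were lower in 6 of 8 cases, by a median of -0.19 (camera adjusted p = 0.00989; adjusted p = 0.418 with an estimated correlation; 0.0975 by camera without sham 13). Antigen presentation genes were higher in 12 of 15 cases, by a median of 0.29 (camera adjusted p = 0.00432; adjusted p = 0.465 with an estimated correlation; 0.115 by camera without blast 9). Ionotropic glutamate receptors were lower in 11 of 15 cases, by a median of -0.08 (camera adjusted p = 0.00807; adjusted p = 0.286 with an estimated correlation; 0.0572 by camera without sham 12). Of the 15 receptors 2 fell when adjusted over the list alone: Gria1, an AMPA receptor subunit, at -0.22 (SE 0.06) and Grin3a, an NMDA receptor subunit, at -0.44 (SE 0.13; adjusted p = 0.0364 for both). All 17 microglial markers were higher, by a median of 0.14 (camera adjusted p = 0.00125; adjusted p = 0.518 with an estimated correlation; 0.0817 by camera without sham 13). Complement genes were higher in 13 of 14 cases, by a median of 0.15 (camera adjusted p = 0.00613; adjusted p = 0.495 with an estimated correlation; 0.089 by camera without blast 9). C3 itself (ENSRNOG00000046834; chromosome 9, 9721105 to 9747167) rose from 10.4 ± 0.24 to 18.2 ± 4.90 CPM when adjusted over that list alone (edgeR adjusted p = 0.0105; log2 fold change 0.80, SE 0.18). Ribosomal protein genes were higher in 37 of 44 cases, by a median of 0.07 (camera adjusted p = 4.1e-07; adjusted p = 0.411 with an estimated correlation). Choroid plexus RNA was high in 1 library, with Ttr at 1609 CPM in blast 9 and at most 15.92 CPM in the other 8. The camera call of that list (13 of 13 higher, median 3.21, adjusted p = 0.00601; adjusted p = 0.593 with an estimated correlation) ended without blast 9 (adjusted p = 0.852).

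Altogether 20 of 40 lists passed in amygdala by camera, 11 up and 9 down, 13 without sham 12 and 0 with an estimated correlation (smallest adjusted p = 0.286). Fry called 0 (smallest adjusted p = 0.233). No gene passed by edgeR (smallest adjusted p = 0.901), with 829 of 15884 genes at an unadjusted p below 0.05 against 794.2 by chance, while DESeq2 called 8 genes. In the authors' deposited values 8 genes pass, 4 up and 4 down, all in the same direction here, where the same counts were used. These values hold no adjusted p for 12820 genes. Groups did not overlap for 271 genes (1.71%, chance 1.587%). Besides C3, the genes of smallest p that were higher included Col5a1, a collagen, at 69.4 ± 4.39 and 87.4 ± 5.16 CPM (ENSRNOG00000008749; chromosome 3, 6430201 to 6578882; log2 fold change 0.33, SE 0.06). Others were Fance, a DNA repair protein, at 0.41 (SE 0.08), Rpl21, Rpl36 and Tnks2. Besides Gad2, lower was Fam131a (ENSRNOG00000045653; chromosome 11, 82875627 to 82884660), at 76.2 ± 26.9 and 10.6 ± 7.64 CPM (-2.86, SE 0.47). Others were Pnpla1 at -2.45 (SE 0.52), the granule protein Scg2 at -0.37 (SE 0.08), Rerg and Nxph1. Each of these had an edgeR adjusted p of 0.901. Without sham 12 edgeR called 1 gene, Pnpla1 (adjusted p = 0.0215, against 0.994 at the highest among the settings tried). Without blast 1 it also called 1 gene. Rpl21, Rpl36 and the Tnks2 gene placed on the unplaced contig AABR07024382.1 share sequence with other copies, so their counts are uncertain.

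In anterior cortex, nuclear genes of the mitochondrial respiratory chain were lower in blast libraries. Those encoded by the mitochondrial genome did not pass, with 7 higher and 6 lower (camera adjusted p = 0.504). Grm2, the metabotropic glutamate receptor that sits before the synapse and restrains glutamate release, was lower as well. Of 34 nuclear genes of oxidative phosphorylation 33 were lower, by a median log2 fold change of -0.19 (camera adjusted p = 3.62e-11; adjusted p = 0.745 with an estimated correlation). The call held whichever library was left out. With a trend with gene length and mean level removed, the median of this list was -0.069 (limma cameraPR adjusted p = 0.0157). The cameraPR test is camera run on the test statistics of the genes, here at the preset correlation. An estimated correlation was not tried for corrected values. Examples were Cox8a at 257 and 199 CPM (-0.37, SE 0.14), Cox4i1 at 423 and 372 CPM (-0.19, SE 0.08) and Ndufv1 at 147 and 129 CPM (-0.19, SE 0.08), none of which passed over the list alone. Ndufa1 had the smallest p of the list and an uncertain count, since it shares sequence with other copies. Grm2 (ENSRNOG00000013171; chromosome 8, 115344999 to 115358046) fell from 39.5 ± 9.54 CPM in 5 sham libraries to 23.4 ± 6.13 CPM in 3 blast libraries when adjusted over the 8 genes fixed by name alone (edgeR adjusted p = 0.0245; 0.842 over all genes). The log2 fold change was -0.76 (SE 0.20).

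Genes of inhibitory neurons were lower here too, in 12 of 14 cases and by a median of -0.22 (camera adjusted p = 0.00733; adjusted p = 0.745 with an estimated correlation; 0.168 by camera without blast 6). The members of smallest p were other ones than in amygdala: Pvalb and Sst, which mark separate classes of these cells, differed by -0.32 (SE 0.13) and -0.38 (SE 0.16), while Gad2 differed by 0.09 (SE 0.08). Striatal markers rose, with 14 of 15 higher and a median of 0.24 (camera adjusted p = 4.95e-05; adjusted p = 0.745 with an estimated correlation; 0.0728 by camera without blast 6). Ribosomal protein genes were lower in 39 of 44 cases, by a median of -0.09 (camera adjusted p = 0.000134; adjusted p = 0.769 with an estimated correlation; 0.177 by camera without blast 5). After a trend with gene length and mean level was removed, the median of ribosomal protein genes was 0.01 and the call ended (cameraPR adjusted p = 0.78). All 15 measured fibroblast and matrix genes were higher, by a median of 0.27 (camera adjusted p = 0.0263; adjusted p = 0.769 with an estimated correlation). This call ended without sham 10, sham 12, blast 5 or blast 6 (adjusted p up to 0.819). In that list Fn1, the matrix protein fibronectin, rose from 60.4 to 97.0 CPM when adjusted over the list alone (adjusted p = 0.0454; log2 fold change 0.69, SE 0.18).

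In this region 11 of 39 lists passed by camera, 7 up and 4 down, and 0 with an estimated correlation (smallest adjusted p = 0.745). The number by camera depended on single libraries. Of the lists 2 passed without blast 6, 6 without sham 16 and 17 without blast 1. Fry called 0 (smallest adjusted p = 0.342). The 1 gene past the threshold by edgeR was AABR07066510.1 (ENSRNOG00000049123; chromosome 9, 9931441 to 9936247), a protein-coding gene with no name that lies outside the naming rule and was chosen after its values were seen. It had no count in 4 of the 5 sham libraries, 0.06 CPM in sham 16, and 2.44, 3.75 and 0.66 CPM in blast 1, 5 and 6 (edgeR adjusted p = 0.0481). With its mean of 15.25 counts no fold is given. No gene was called without sham 10, sham 12, sham 16 or blast 1 (0 genes each), and 2 genes were called without sham 18 or blast 5. At an unadjusted p below 0.05 there were 917 of 15765 genes, where chance gives 788.2, and 665 genes did not overlap (4.22%, chance 3.571%). DESeq2 called 12 genes, and in the authors' deposited values 3 pass, 1 up and 2 down.

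Among the genes of smallest p in anterior cortex, Tsc22d4 (ENSRNOG00000050805; chromosome 12, 22009011 to 22021851) was at 2.69 ± 0.57 CPM in sham and 6.998 ± 1.77 CPM in blast libraries (log2 fold change 1.37, SE 0.24; edgeR adjusted p = 0.768). Fundc2 was at 29.6 ± 3.64 and 18.1 ± 2.71 CPM (-0.71, SE 0.13; edgeR adjusted p = 0.785). The authors' deposited adjusted p for these genes are 0.0078 and 0.0090. Adgre1, a macrophage and microglial surface receptor, was higher by 0.46 (SE 0.11), and the protocadherin Pcdh17, Fam149a, Tanc1 and Anp32a by 0.41 to 0.66. Lower were Mgst3, a membrane-bound glutathione transferase, at -0.38 (SE 0.08), Catsperz, Tpi1, Atoh7 and Frmd7, at -0.34 to -3.11, all with an adjusted p of 0.842. Tpi1 has processed copies elsewhere in the genome, so its count is uncertain.

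**Figure D2:**
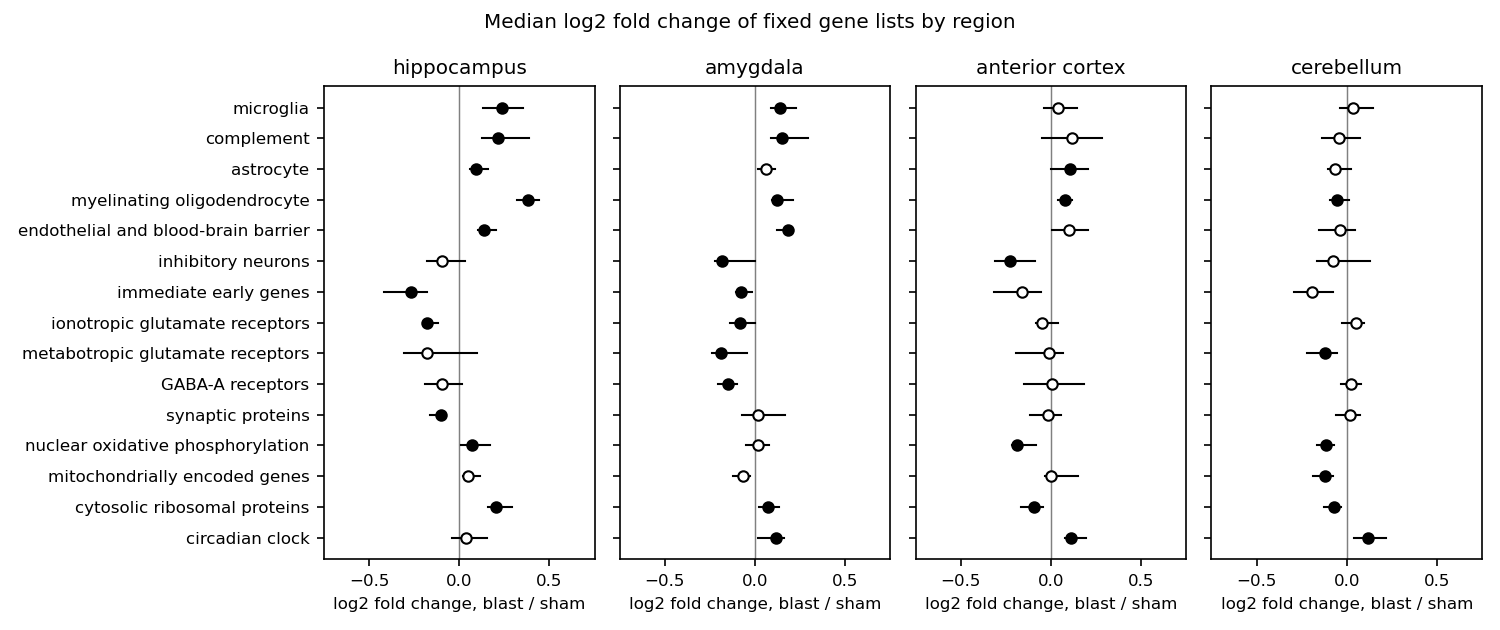
Each point is the median log2 fold change (blast over sham) of the measured genes of 1 list in 1 region, the line spans the middle 50% of its genes, and filled points passed camera at its preset correlation. The microglial median is 0.24 in hippocampus and 0.04 in anterior cortex and cerebellum, and the ribosomal protein median runs from 0.20 in hippocampus to -0.09 in anterior cortex.

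In cerebellum, which coordinates movement, the gene of smallest p among those the naming rule takes was Grm2, which there is found mainly in Golgi cells and unipolar brush cells. It fell from 15.6 ± 2.20 CPM in 4 sham libraries to 7.94 ± 1.40 CPM in 5 blast libraries when adjusted over the 8 genes fixed by name alone (edgeR adjusted p = 0.000148), a log2 fold change of -0.97 (SE 0.14). Every blast library lay below every sham library. Over all genes its adjusted p was 0.141 by edgeR and 1.11e-06 by DESeq2, with a range of 1.11e-06 to 0.502 over the settings tried. DESeq2 was the 1 of 17 settings in which it passed. Its family fell as a list, with 6 of 8 metabotropic glutamate receptors lower and a median of -0.12 (camera adjusted p = 0.0179; adjusted p = 0.329 with an estimated correlation; 0.119 by camera without sham 10). Grm8 was the other member to pass over the list alone, at -0.33 (SE 0.10; edgeR adjusted p = 0.0268).

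**Figure D3:**
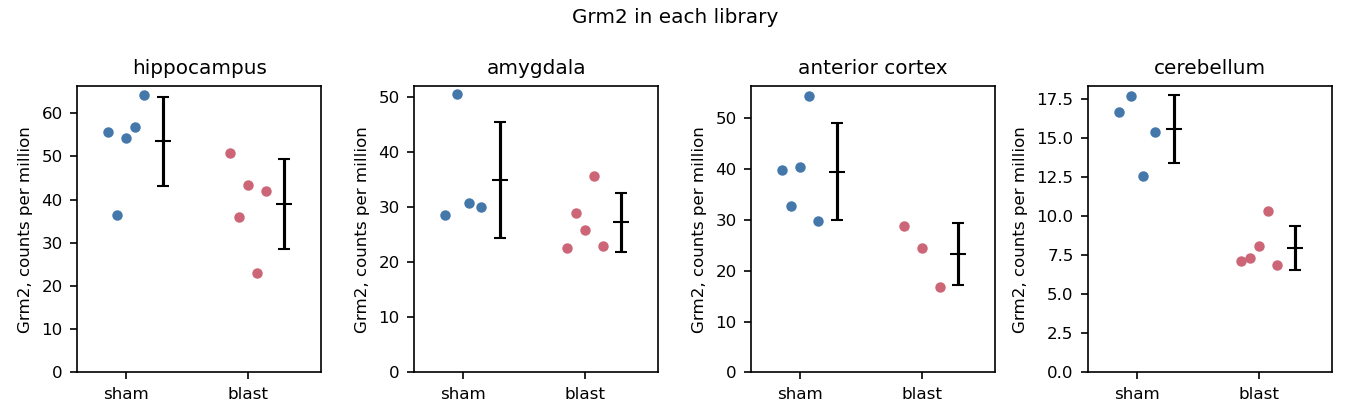
Each point is 1 library (blue sham, red blast), the vertical axis is Grm2 in CPM, and the bars give the group mean and SD. In cerebellum the blast libraries lie between 6.86 and 10.31 CPM and the sham libraries between 12.58 and 17.65 CPM, and the blast mean is below the sham mean in all 4 regions.

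Nuclear genes of the respiratory chain were lower in cerebellum as in anterior cortex. Of 34 nuclear genes of oxidative phosphorylation 32 were lower, by a median of -0.11 (camera adjusted p = 5.7e-13; adjusted p = 0.329 with an estimated correlation), whichever library was left out. With the trend with gene length and mean level removed, this median was -0.045 (cameraPR at the preset correlation, adjusted p = 0.012). An estimated correlation was not tried for corrected values. Atp5mc1, a subunit of ATP synthase, at -0.24 (SE 0.05), Ndufa4 at -0.16 (SE 0.04) and Ndufb5 at -0.19 (SE 0.05) were the 3 members to pass over the list alone (edgeR adjusted p = 0.0233, 0.029 and 0.0476). Of the genes encoded by the mitochondrial genome 12 of 13 were lower, by a median of -0.12 (camera adjusted p = 0.00075; adjusted p = 0.809 with an estimated correlation; 0.144 by camera without sham 18). In anterior cortex their median was 0. By camera with an estimated correlation no list differed between these 2 regions (smallest adjusted p = 0.858). Ribosomal protein genes were lower in 36 of 43 cases, by a median of -0.07 (camera adjusted p = 0.000106; adjusted p = 0.809 with an estimated correlation; 0.0732 by camera without sham 13). After a trend with gene length and mean level was removed, the median of ribosomal protein genes was -0.008 and the call ended (cameraPR adjusted p = 0.931). Circadian clock genes rose, with 13 of 16 higher and a median of 0.12 (camera adjusted p = 0.0361; adjusted p = 0.809 with an estimated correlation). That call ended without sham 13, sham 16, blast 2, blast 6 or blast 9 (adjusted p up to 0.261). The rise was not particular to cerebellum. From sham to blast the mean log2 CPM of clock genes went from 5.971 to 6.073 in amygdala and from 5.922 to 6.018 in anterior cortex. In hippocampus it went from 5.877 to 5.923. Choroid plexus RNA varied within both groups, with Ttr between 2.21 and 2509 CPM in sham and between 0.11 and 1680 CPM in blast libraries. All 15 of its markers were lower, by a median of -0.89 (camera adjusted p = 0.00402; adjusted p = 0.809 with an estimated correlation). That call ended without sham 13, sham 18, blast 2 or blast 6 (adjusted p up to 0.246).

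By camera 8 of 39 lists passed in cerebellum, 2 up and 6 down, 5 without sham 16, sham 18, blast 2 or blast 6, and 0 with an estimated correlation (smallest adjusted p = 0.329). Fry called 0 (smallest adjusted p = 0.123). No gene passed by edgeR (smallest adjusted p = 0.141), with 1038 of 15225 genes at an unadjusted p below 0.05 against 761.2 by chance and 336 genes that did not overlap (2.21%, chance 1.587%), while DESeq2 called 39 genes. In the authors' deposited values 33 genes pass, 19 up and 14 down, all in the same direction here, where the same counts were used. These values hold no adjusted p for 13613 genes, Grm2 among them. Leaving out 1 library, edgeR called 1 gene without sham 10, sham 13, blast 1 or blast 5 and 2 genes without sham 18. Of the 39 genes DESeq2 called, 29 are also past the threshold in the authors' deposited table. Higher was Ak5, a neuronal adenylate kinase (ENSRNOG00000046947; chromosome 2, 257671772 to 257864385), at 24.7 ± 4.5 and 39.9 ± 6.19 CPM (log2 fold change 0.69, SE 0.13). Also higher were the histone acetyltransferase Crebbp (ENSRNOG00000005330; chromosome 10, 11595044 to 11721039), at 99.2 ± 8.61 and 127.9 ± 12.35 CPM (0.37, SE 0.07), and the nuclear receptor partner Nrip1 at 0.20 (SE 0.04), Mybpc3, Plekha5 and Spag5. Besides Grm2, lower were Rgs4, which shortens signals from G protein-coupled receptors, at -0.23 (SE 0.05), Mras at -0.26 (SE 0.05), the peroxide-removing enzyme Prdx2 at -0.20 (SE 0.04), the complex I subunit Ndufc1 at -0.34 (SE 0.07) and RT1-M6-2 at -3.10 (SE 0.58). Their edgeR adjusted p were 0.472 to 0.473. RT1-M6-2 is one of many similar class I genes of the rat major histocompatibility complex, so its count is uncertain.

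The other genes fixed by name gave no call in any region by edgeR, over all genes or over the 8 genes alone. Gfap, the astrocyte filament gene that rises with gliosis, differed by 0.03 (SE 0.11) in hippocampus, 0.07 (SE 0.20) in amygdala, -0.05 (SE 0.19) in anterior cortex and -0.18 (SE 0.08) in cerebellum. The microglial gene Aif1 differed by 0.35 (SE 0.19), 0.20 (SE 0.17), 0.13 (SE 0.18) and 0.05 (SE 0.18), and Vwf, made by endothelium, by 0.10 (SE 0.13), 0.36 (SE 0.14), 0.40 (SE 0.20) and 0.13 (SE 0.09) in the same order. Grm3, Mapt, which encodes tau, Fkbp5, a target of glucocorticoids, and Fos had log2 fold changes between -0.95 and 0.30. Grm2 differed by -0.45 (SE 0.19) in hippocampus and -0.36 (SE 0.18) in amygdala, where it did not pass over the 8 genes alone (adjusted p = 0.304 and 0.261).

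Whether blast acted differently by region was tested over all 36 libraries. The effect on 2 of 17120 genes differed between regions by edgeR's quasi-likelihood test of the region by treatment terms (Benjamini-Hochberg adjusted p = 0.0166 for both), RT1-M6-2 and LOC108348106, the latter chosen after its values were seen. LOC108348106 (ENSRNOG00000025216; chromosome 1, 88766872 to 88772242) was at 5.37 ± 3.06 CPM in sham and 0.21 ± 0.13 CPM in blast libraries of cerebellum, and at 0.78 ± 0.40 and 1.04 ± 0.39 CPM in amygdala. With the number in the title as a block 0 genes passed (smallest adjusted p = 0.211), with 902 at an unadjusted p below 0.05 against 856 by chance. For Grm2 the difference between regions did not pass (adjusted p = 0.938).

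Ribosomal protein genes rose in hippocampus by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.462). Their median there was 0.185 once the trend with gene length and mean level was removed. Their fall in anterior cortex and cerebellum ended with that correction (medians 0.01 and -0.008). Without it their changes in hippocampus exceeded those in anterior cortex by a median of 0.31 and those in cerebellum by 0.27 (camera on the difference, adjusted p = 1.97e-22 and 3.48e-22; adjusted p = 0.858 with an estimated correlation for both). Nuclear genes of oxidative phosphorylation, of which 29 of 34 were higher in hippocampus (median 0.07; camera adjusted p = 0.000281; adjusted p = 0.462 with an estimated correlation; 0.107 by camera without sham 16), differed between the same regions by 0.249 and 0.205 (adjusted p = 2.33e-14 and 1.03e-11; adjusted p = 0.858 with an estimated correlation for both). The changes of ionotropic glutamate receptors in hippocampus and cerebellum differed by a median of -0.25 (adjusted p = 0.000315; adjusted p = 0.858 with an estimated correlation). Those of immediate early genes in hippocampus and amygdala differed by -0.15 (camera adjusted p = 0.0133, and 0.91 with an estimated correlation). Their differences from hippocampus to anterior cortex and cerebellum, -0.179 and -0.193, did not pass (camera adjusted p = 0.0654 and 0.0987). The mean score of this list was lower in blast than in sham libraries in all 4 regions. The lists whose change differed between a pair of regions numbered 10 for hippocampus and amygdala, 5 for hippocampus and anterior cortex, 14 for hippocampus and cerebellum, 3 for amygdala and anterior cortex, 10 for amygdala and cerebellum and 5 for anterior cortex and cerebellum, of 40 each, and 0 in every pair with an estimated correlation.

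Across genes, which are not independent replicates, the log2 fold changes of hippocampus and amygdala correlated most (Pearson's r = 0.221 over 15180 genes, jackknife SE 0.101). When the numbers were relabelled as blast or sham, the median r was 0.104 and 1 of 100 draws gave a value as large. Without blast number 9 r was 0.119, close to that median. The other 5 pairs of regions lay between -0.118 for hippocampus and cerebellum and 0.145 for anterior cortex and cerebellum. For these 13 to 92 of 100 relabellings gave values as large, so these correlations did not exceed what shared numbers alone give. No adjustment over the 6 pairs was made for these counts.

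**Figure D4:**
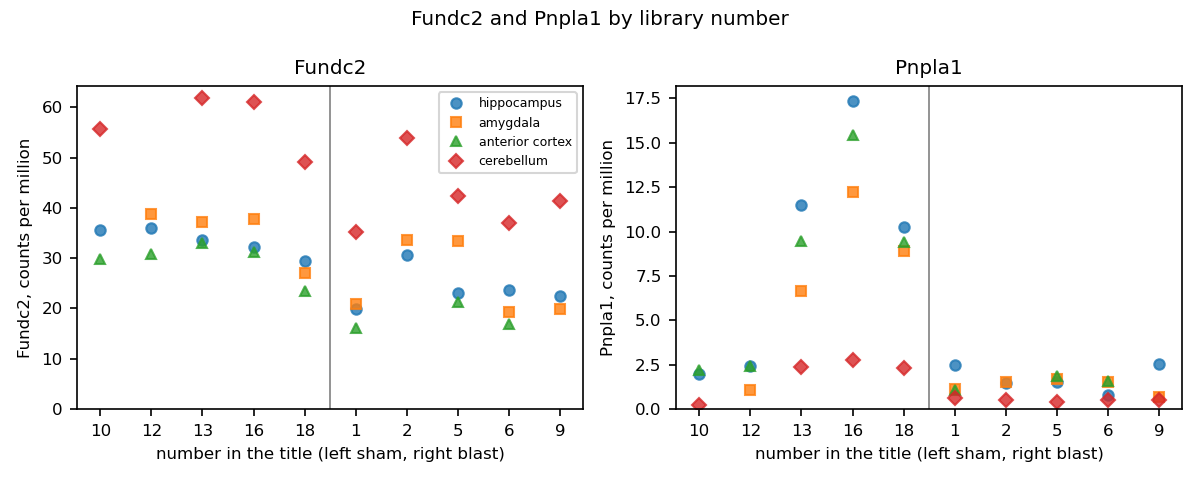
Each point is 1 library, the horizontal axis gives the number in its title (sham left, blast right), the vertical axes give Fundc2 and Pnpla1 in CPM, and symbols mark the region. In hippocampus Pnpla1 reaches 17.34 CPM among sham and at most 2.51 CPM among blast libraries, and sham 13, 16 and 18 lie above sham 10 and 12.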

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

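The tests of a variant and of an effect common to regions, of gene length and of differences of lists between regions, and the count of splits for genes by number, were chosen only after the result was seen. Chance makes about 1 in 20 groups of libraries hold a value far from the others: 18 of 257 groups did, where 12.9 are expected. In hippocampus sham 12 lay apart with the lowest score of dentate granule cells (6.064) and the highest Ccdc152 (13.84 CPM) and Fkbp5 (77.46 CPM), and blast 6 with the highest myelin score (8.819), the lowest synaptic (8.089) and axonal (8.604) scores and the highest Lsp1 (5.349 CPM). In amygdala sham 13 had the highest score of metabotropic glutamate receptors (5.057) and Grm2 (50.5 CPM), sham 12 the highest score of ionotropic glutamate receptors (6.68) and blast 9 the highest choroid plexus (5.832) and ribosomal protein (6.961) scores. In anterior cortex sham 16 had the lowest mitochondrial share (12.81%) and sham 18 the lowest Tpi1 (8.352 CPM). In cerebellum Fos was highest in sham 18 (36.25 CPM) among sham and in blast 5 (15.18 CPM) among blast libraries, Crebbp in blast 1 (149.3 CPM) and Fkbp5 in blast 6 (26.34 CPM).

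Other results stood out because the effect of blast differed between regions. By edgeR's test over the 4 regions this held for LOC108348106 and RT1-M6-2 (adjusted p = 0.01658 for both; 0.211 with the number as a block). By camera at its preset correlation a difference between 2 regions held for myelin genes (adjusted p = 0.00019), choroid plexus (2.28e-10) and dentate granule cells (0.0394) between hippocampus and cerebellum, choroid plexus between amygdala and cerebellum (0.000251) and striatal markers between amygdala and anterior cortex (0.00019). Oxidative phosphorylation genes differed between hippocampus and anterior cortex (2.33e-14) and cerebellum (1.03e-11). Ribosomal protein genes differed between hippocampus and anterior cortex (1.97e-22) and cerebellum (3.48e-22), and between amygdala and anterior cortex (2.58e-08) and cerebellum (8.9e-09). No list differed with an estimated correlation (smallest adjusted p = 0.858).

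Grm2 was lower in blast libraries of 4 regions. In cerebellum a loss of Golgi cells is argued against by markers added after the Grm2 result was seen, with a median log2 fold change of -0.047. Slc6a5 was at 0.043 (SE 0.054), Lgi2 at -0.065 (SE 0.055) and Sorcs3 at -0.047 (SE 0.056). Markers of unipolar brush cells had a median of -0.052, with Calb2 at 0.127 (SE 0.1). Calb2 was at 415 CPM in sham libraries, against 13.9 CPM for Eomes and 4.28 CPM for Lmx1a, so it may not report these cells alone. Eomes (-0.052, SE 0.305) and Lmx1a (-0.218, SE 0.51) were too variable to exclude a partial loss. These markers therefore do not decide for unipolar brush cells. Reads of an overlapping gene are argued against, the nearest gene lying 2667 bp away. If the numbers mark animals, a variant carried by some animals of each group is argued against by the share of variance that follows the number, -0.063 above chance. A variant that separates the groups stays open. An effect of blast common to the regions stays open too: averaged by number, blast minus sham was -0.61, with an exact p of 0.00794, the smallest that 252 relabellings can give. Adjusted over the 8 fixed genes that is 0.0635, and a gene alone at the smallest p cannot get below it, so this test does not decide.

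Fundc2 and Pnpla1 were lower in blast libraries of several regions, and Fam131a and Tnks2 were high in some libraries and low in others. For Fundc2 and Pnpla1 the number accounted for 0.802 and 0.865 of the variance within groups, where chance gives 0.279 and 0.281. The permutation p was 1e-04 for both, the smallest these permutations can give. A variant carried by some animals is a candidate if the numbers mark animals, but any other factor that follows the number would give the same. The share pools both groups, so it does not show high and low animals in each. In hippocampus Pnpla1 was at 1.971 to 17.34 CPM in sham but at 0.7882 to 2.514 CPM in blast libraries. For Fam131a and Tnks2 a variant carried by some animals is argued against by a share of at most 0.047, again only if the numbers mark animals. Reads shared with Fam131c are argued against by its r of -0.173 with Fam131a, while the r of 0.073 of Tnks2 with the more abundant Tnks decides less. Reads shared with a copy outside the tables stay open: the lowest r with any gene was -0.667, for Fam131a with Tnfrsf9, but no second gene of either symbol is in the tables and a more abundant copy would barely move, so the bound set beforehand was wrong. No biological explanation was tested for these genes.

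By camera at its preset correlation ribosomal protein and oxidative phosphorylation genes rose in hippocampus and fell in anterior cortex and cerebellum, though no call held with an estimated correlation (adjusted p = 0.329 to 0.809). They are short (median 718 and 837 bp, against 2321 bp for all genes in hippocampus), but gene length is argued against as the whole cause in hippocampus, where the lists kept at least 0.856 of their medians after the trend with length and level was removed. In anterior cortex and cerebellum a length bias may explain the fall of ribosomal protein genes, which kept at most 0.114 of their medians (cameraPR adjusted p = 0.78 and 0.931 afterwards). For oxidative phosphorylation genes it stays open, since they kept at least 0.372. Their medians moved from -0.186 to -0.069 and from -0.113 to -0.045 (cameraPR adjusted p = 0.0157 and 0.012 afterwards). Both p-values are at the preset correlation, and an estimated correlation was not tried for corrected values. Whether blast acts on both lists differently by region stays open as well (adjusted p = 0.858 with an estimated correlation).

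The libraries were also split into groups of the same sizes in other ways, and each tally here includes the real split. For genes 100 of 100 splits gave at least as many calls in hippocampus (0 in the real split, at most 1 in another), amygdala (0, 2), cerebellum (0, 70) and by number (0, 1), which a real count of 0 makes certain, so these tallies decide nothing. Chance is not excluded for the 1 gene in anterior cortex (26 of 56 splits; 1, 61) or for the lists in hippocampus (14 of 100; 19, 22), anterior cortex (28 of 56; 11, 22), cerebellum (41 of 100; 8, 18) and by number (8 of 100; 19, 22). For the lists in amygdala (5 of 100; 20, 23) and the genes that differed between regions (2 of 40; 2, 158) it is not excluded either, but these lie at the limit of 0.05, which they reach only with the real split included. The splits that called 70 genes in cerebellum and 158 between regions point to a structure of the samples other than blast and sham. They had 1359 and 2434 genes at an unadjusted p under 0.05 (761.2 and 856 by chance). In cerebellum this split grouped sham 10, sham 13, sham 18, blast 1 and blast 5, where Ttr was at 522.8 to 2509 CPM. In the remaining libraries Ttr was at 0.1103 to 58.09 CPM, so the split separated libraries by choroid plexus RNA. For the split between regions the structure was not tested. The split with 61 calls may reflect a structure in few genes only, since it had 753 at that p, where chance gives 788.2. Beside the counts of 0, edgeR gave 805, 829 and 1038 genes at an unadjusted p under 0.05 and DESeq2 called 1, 8 and 39 genes in hippocampus, amygdala and cerebellum; by number limma gave 1254.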

How the results depend on the processing

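The robust spread estimate and the choroid plexus score as a covariate were chosen after seeing the data, and where a value moved the cause was not tested. DESeq2's Wald test called 1, 8, 12 and 39 genes in hippocampus, amygdala, anterior cortex and cerebellum, against 0, 0, 1 and 0 by edgeR. In anterior cortex 0 genes passed with voom quality weights, a mean of at least 50 counts or 1 surrogate variable and 2 with no filter, and in cerebellum 1 passed with no filter and 1 with 1 surrogate variable. Leaving out 1 library gave 0 to 1 genes in hippocampus and amygdala and 0 to 2 in anterior cortex and cerebellum, and 11 to 21, 13 to 22, 2 to 17 and 5 to 12 lists in the 4 regions. With an estimated correlation and by fry 0 lists passed in each region, and with the choroid plexus covariate 7 in hippocampus. With the number as a block 0 genes differed between regions. In 48 pairs of libraries of the same number in 2 regions, residuals correlated at a median of 0.11. Of these 22 of 24 sham pairs but 11 of 24 blast pairs correlated best with their own number. With 3 to 5 libraries of a group to choose from, both counts lie above chance, which favours numbers that mark animals. The blast pairs were uneven, though, and pairs share libraries. Between hippocampus and cerebellum blast 1, 2, 5, 6 and 9 each correlated better with another number (blast 6 at -0.068 with its own, 0.337 with another). Between amygdala and cerebellum blast 1, 2, 5 and 6 correlated best with their own. The labels do not say that numbers mark animals and no p-value was computed, so this stays open, most of all for hippocampal blast libraries. Among genes above the median of expression in both regions r was 0.411 for hippocampus and amygdala (median 0.137 over 100 relabellings, 3 of them as large), 0.318 for anterior cortex and cerebellum (0.165, 7), -0.25 for hippocampus and cerebellum (-0.007, 20), 0.194 for hippocampus and anterior cortex (0.105, 46), 0.03 for amygdala and anterior cortex (0.03, 81) and -0.054 for amygdala and cerebellum (0.125, 77). These relabellings were added after the data were seen. None of the genes taken by the naming rule passed over all genes in its region, so none had a call to lose: of 764 comparisons with an alternative, 24 newly passed, 21 reversed and 719 stayed short of the threshold in the same direction. With 1 surrogate variable Gfap in hippocampus was at -0.096, Grm3 in amygdala at -0.041 and Fkbp5 in cerebellum at -0.004; with the choroid plexus covariate Gfap was at -0.108 and Fkbp5 at -0.006; with voom weights Fkbp5 in amygdala was at -0.01 and Gfap in anterior cortex at 0.019. Leaving out 1 library gave, in hippocampus, Gfap -0.019 to 0.09 and Mapt -0.057 to 0.005; in amygdala, Gfap -0.149 to 0.181, Grm3 -0.078 to 0.227 and Fkbp5 -0.052 to 0.05; in anterior cortex, Gfap -0.381 to 0.209, Aif1 -0.069 to 0.251, Mapt -0.088 to 0.001 and Fos -0.718 to 0.098; in cerebellum, Aif1 -0.034 to 0.147, Grm3 -0.018 to 0.063, Mapt -0.053 to 0.038, Fkbp5 -0.027 to 0.062 and Fos -1.736 to 1.077. Another pseudocount does not apply to counts and was not run. On simulated data with 1.5-fold changes 38.8% to 55.2% of changed genes were recovered per region, so small changes can be missed. These rates hold for many genes changed at once and would be lower where few genes change.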

Other observations

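The tests over all regions, by number and with a correlation within numbers, were chosen only after the results by region were seen. Averaged over regions by number (5 blast, 5 sham), genes of inhibitory neurons were lower for blast numbers in 13 of 15 cases, by a median of -0.12 (limma camera adjusted p = 0.000103; adjusted p = 0.146 with an estimated correlation), and 4 of them passed when adjusted over the list alone. All 20 immediate early genes were lower, by a median of -0.21 (adjusted p = 4.65e-06; 0.419 with an estimated correlation), and 16 of 17 microglial markers higher, by 0.14 (adjusted p = 1.35e-05; 0.419 with an estimated correlation). Genes of other cell types moved too: all 15 choroid plexus markers were higher, by a median of 0.65 (adjusted p = 3.26e-06, the smallest of all lists; 0.433 with an estimated correlation), as were all 15 fibroblast and matrix genes and all 17 myelin genes (adjusted p = 0.000215 and 0.00156; 0.447 and 0.543 with an estimated correlation). Of the 40 lists 19 passed at the preset correlation and 0 with an estimated one. No gene passed by limma (smallest adjusted p = 0.235), with 1254 of 17120 at an unadjusted p under 0.05 against 856 by chance for independent genes. Of 99 other splits of the numbers 10 gave more than 1254, up to 2342, so this count is not beyond relabelling. There were 213 genes whose groups did not overlap (1.24%, chance 0.794%).

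With all 36 libraries in 1 limma-voom fit and a correlation within numbers (estimated at 0.028), 10 of 17120 genes passed and 1474 had an unadjusted p under 0.05. They were Fundc2 (log2 fold change -0.52, adjusted p = 0.000445), the matrix gene Fn1 (0.50, 0.0113), Pigk (0.26, 0.0113), the interferon-induced gene Ifi44l (-1.39, 0.0155), Fance (0.23, 0.0155), Mir193b (3.33, 0.0155), the interferon receptor gene Ifnar1 (0.15, 0.0155), C3 (0.60, 0.0304), Grm2 (-0.55, 0.0454) and the glucose transporter gene Slc2a4 (0.48, 0.0476). Genes outside the naming rule were chosen after their values were seen. Mir193b did not pass the count filter when anterior cortex was tested alone, so its fold may rest on few counts and is uncertain. C3 was higher by 0.73, 0.80, 0.51 and 0.40 in hippocampus, amygdala, anterior cortex and cerebellum, and Fn1 (ENSRNOG00000014288; chromosome 9, 78900103 to 78969078) by 0.52, 0.45, 0.69 and 0.33. This fit treats libraries of a number as nearly independent, so its p-values are smaller than those by number.

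The number in the title accounted for more of the variance within groups than chance in 5 of 53 named genes (10000 permutations, Benjamini-Hochberg): Pnpla1, Fundc2, Col5a1 (share 0.627, by chance 0.28), Fos (0.654, by chance 0.278) and Mapt (0.613, by chance 0.275). For Pnpla1, sham 13, 16 and 18 lay above sham 10 and 12 in every region in which they were measured.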
